A study of Mus musculus with 18 samples.

How the data were processed

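RNA was sequenced from E14 mouse embryonic stem cells grown on gelatin in medium with 15% serum and leukaemia inhibitory factor at 10 ng/ml, per the labels. Wild-type cells (Wt) and cells lacking GCN2 (Gcn), the eIF2α kinase encoded by Eif2ak4 that senses uncharged tRNA, were starved of arginine or of leucine for 3 h, or kept unstarved. Starvation used SILAC medium with 5% dialyzed serum, and the unstarved cells received the same kind of medium with all amino acids. Each of the 6 groups held 3 replicates (18 libraries). Per the labels' protocols, libraries were made from 1 µg of total RNA with a directional poly(A) kit, pooled in 1 sequencing kit and read as 2 reads of 43 bp per fragment. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

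Per the submitters' processing notes, the tools used before deposit included bcl2fastq, FastQC 0.11.7, STAR 2.7.4a, HTSeq, DESeq2, DESeq 1.30.1 and R 4.0.3, with the mouse build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes may therefore be assigned differently from a strand-aware count. Reads of near-identical family members (Zscan4, Usp17l, Xlr3, Slfn, histone and Hspa1 genes) were counted by rules also not given, so these genes are uncertain. The deposited count tables, 1 per genotype, hold raw whole-number counts per Ensembl gene for 9 libraries each. The authors also deposited 2 normalized tables, whose values are a signal equal to the count divided by 1 size factor per library, computed separately in each genotype. The largest relative departure from that reading was 0. These tables hold the 28187 genes (Wt) and 28439 genes (Gcn) with at least 2 counts over the 9 libraries, and they entered no test. Of the 55471 gene identifiers, 55144 were matched to a symbol in GENCODE vM21, and the other 327 held at most 0.015% of any library's counts. No entry of the tables named anything but a gene. 5 symbols were shared by several tested identifiers.

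Library totals ran from 14.8 M to 38.8 M (mega) counts. CPM are counts divided by the library total in M, scaled by the trimmed mean of M values (TMM). Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1, statmod 1.5.0): filterByExpr with default settings, TMM scaling, robust dispersion estimates and the quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another tool is named, and each SE is the size of the log2 fold change divided by the square root of F. The 4 comparisons of a starved with an unstarved group and the comparison of leucine with arginine starvation used the 9 libraries of 1 genotype (16140 genes in Wt and 16369 in Gcn). The comparison of the unstarved genotypes and both interactions (the change in Gcn minus the change in Wt) used all 18 libraries and 16924 genes. The biological coefficient of variation of a gene of median dispersion was 0.08 in the Wt fit, 0.114 in the Gcn fit and 0.101 over all libraries. Genotype and culture history cannot be separated. Principal components were computed from log2 CPM with a prior count of 2.

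Groups of genes were tested with camera of limma at a preset correlation of 0.01, with adjustment over the 27 lists within each comparison, and again with the correlation estimated from the data. Fry, run as an alternative, called 15, 16, 15 and 13 lists (Wt Arg, Wt Leu, Gcn Arg, Gcn Leu), 6 and 0 (leucine against arginine in Wt and Gcn, with 7 and 6 at an unadjusted p under 0.05), 17 (unstarved genotypes) and 5 and 6 (interactions), where camera called 13, 12, 18, 12, 7, 1, 9, 8 and 11. Calls lost with fry were ribosomal proteins (Wt Arg, Wt Leu, Gcn Arg and Wt leucine against arginine), two-cell-like genes, p53 targets and histones (Gcn Arg), heat shock and glycolysis (Gcn Leu), ISR regulators (Wt leucine against arginine), lysosome and autophagy (Gcn leucine against arginine), fatty acid synthesis and p53 targets (both interactions), glycolysis (arginine interaction), and immediate early, ribosome biogenesis and mitochondrial genes (leucine interaction). The lists are ISR regulators (integrated stress response), amino acid synthesis, tRNA synthetases, amino acid transporters, arginine and polyamine metabolism, leucine catabolism, sterol synthesis, fatty acid synthesis, lysosome and autophagy, immediate early genes, ERK feedback, naive pluripotency, primed and lineage markers, two-cell-like genes, fibroblast markers, ER chaperones, heat shock, NRF2 antioxidant genes, p53 targets, ribosomal proteins, ribosome biogenesis, replication, mitosis, glycolysis and hypoxia, interferon response, and histone and mitochondrial genes as signs of RNA quality. With the estimated correlation, 11 of the 91 list calls held: ISR regulators and amino acid transporters in both interactions, tRNA synthetases and ER chaperones in the arginine interaction, and immediate early genes, primed and lineage markers, two-cell-like genes, fibroblast markers and ER chaperones between the unstarved genotypes.

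The groups, tests, lists, the rule for naming genes and all alternatives except those called added were chosen before the data were examined. For each starvation, the rule names the 8 highest and 8 lowest fold changes among called genes with a mean of at least 5 CPM whose 3 starved libraries all lay on the same side of the 3 unstarved ones. It adds the 3 members of each called list with the smallest adjusted p, and Eif2ak4, Atf4, Ddit3, Trib3, Asns, Chac1, Sesn2 and Ddit4. These 8 were also run between the unstarved genotypes and, without Eif2ak4, in the interactions (added after the data were seen). For each other comparison it names the 6 highest and 6 lowest. In those comparisons the examples given from a list were chosen after their values were seen and were not run under the alternatives.

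The alternatives were no filter on low counts (at least 1 count in all), a filter at 1 CPM in 3 libraries, relative log expression (RLE) scaling, library size only, DESeq2 1.42.0, limma-voom, a replicate block, a log2 fold change of at least 1 as well, only the compared groups or all 6 groups in the fit, and each library left out in turn. A GC correction (a lowess curve with a span of 0.3 of each library's log ratio on GC content of the coding sequence) and fits without the 3 Gcn libraries numbered 1 were added after the data were seen. Replicate numbers, shared between groups in the labels, entered no main fit. They were taken to pair samples where every same-numbered pair of compared groups correlated above 0.1 in deviations from group means. This held for arginine starvation in Wt (0.111 to 0.231) and Gcn (0.186 to 0.482), leucine starvation in Gcn (0.212 to 0.499), and leucine against arginine starvation in Wt (0.2 to 0.32) and Gcn (0.334 to 0.523). Replicates of a group differed by a chi-square of 7.46 to 35.64 per degree of freedom over 18 pairs, so no library was a copy of another.

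Codon shares were taken from the longest coding sequence of each of 20954 genes with at least 100 codons, and correlated across genes with fold changes (Spearman), with 100000 permutations (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3) adjusted over the 20 amino acids. Partial correlations control for GC content, GC at wobble positions, coding length and mean expression. Figures were drawn with matplotlib 3.10.9.

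The tests were run on simulated data with 200 changed genes. In Wt Arg, 50 of 67 genes changed 1.5-fold, 55 of 67 changed 2-fold and 63 of 66 changed 4-fold were called. So were 21 of 15920 unchanged genes. In Gcn Arg the counts were 30, 52 and 63, with 15 of 16149 unchanged. For the arginine interaction (16924 genes) they were 14, 44 and 57, with 8 of 16704, so differences of 1.5-fold between genotypes were mostly missed. False calls exceeded the set share of 0.05 in Wt Arg and Gcn Arg. With preset and estimated correlation, a planted list of 20 genes was called in all 3 comparisons and 0 of 26 random lists were. Lists of correlated genes were not simulated. In simulated fold changes of 20954 genes, a planted correlation of 0.2 with arginine share gave 0.197 (partial 0.18), and one planted on GC content gave 0.07 for arginine (partial -0.015).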

Results

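Gene expression was measured in E14 mouse embryonic stem cells with GCN2 (Wt) and without it (Gcn) after 3 h without arginine, 3 h without leucine, or in complete medium. The 6 groups held 3 libraries each. Total counts per group averaged 25.6 ± 4.1 M in Wt Unstarved, 28.9 ± 3.4 in Wt Arg, 24.7 ± 5.7 in Wt Leu, 26.5 ± 2.2 in Gcn Unstarved, 20.4 ± 5 in Gcn Arg and 32.3 ± 5.8 in Gcn Leu (SD, n = 3 each). The shallowest library was Gcn Arg 3 and the deepest Gcn Leu 3. The first principal component of log2 CPM parted the genotypes and carried 41.6% of the variance, and the next parted starved from unstarved libraries with 20%. Among the Gcn libraries, the 3 numbered 1 stood apart on a component with 19.8% of the variance (-27.1 to -22.2, against 6.36 to 16.9 for the other 6). Gm42418, a gene overlapping ribosomal RNA sequence, took 0.62% ± 0.52 of the counts in Wt Unstarved and 2.57% ± 1.27 in Gcn Unstarved (SD, n = 3). Mitochondrial transcripts took group means of 2.24% to 2.7%.

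Eif2ak4, the gene encoding GCN2, stood at 29.4 ± 2.1 CPM in the 9 Wt libraries (SD, range 27 to 33.4, 575 to 961 counts) and at 5.12 ± 0.85 CPM in the 9 Gcn libraries (range 4.04 to 6.37, 88 to 215 counts), a 5.75-fold difference with no overlap. By group it averaged 31.8 ± 1.9, 28.9 ± 0.26 and 27.6 ± 0.56 CPM in Wt Unstarved, Arg and Leu, and 5.23 ± 0.87, 5.47 ± 1 and 4.66 ± 0.71 CPM in the same Gcn groups (SD, n = 3). Between unstarved groups its log2 fold change was -2.61 ± 0.13, adjusted p = 1.73e-12, or 6.1-fold lower in Gcn. It was not called with arginine starvation in Wt (-0.13 ± 0.07, adjusted p = 0.135), except with the replicate block and a GC correction together (log2 -0.18, adjusted p = 0.0111), or with either starvation in Gcn (0.07 ± 0.18, adjusted p = 0.816 for arginine, -0.15 ± 0.18, adjusted p = 0.621 for leucine). With leucine starvation in Wt it fell slightly (-0.21 ± 0.07, adjusted p = 0.0341), a call lost without Wt Unstarved 1, Wt Unstarved 2, Wt Leu 1, Wt Leu 2 or Wt Leu 3 (highest adjusted p = 0.102), with no filter on low counts, with library size only, and with only the 2 compared or all 6 groups in the fit (highest adjusted p = 0.209).

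On build GRCm38, Eif2ak4 lies on chromosome 2 from 118388618 to 118475234, the same chromosome as Chac1 (119351229 to 119354381) and Trib3 (152337422 to 152344032).

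In wild-type cells, arginine starvation raised Bhlhe41, a transcriptional repressor, from 4.52 ± 0.13 to 63.3 ± 8.5 CPM (SD, n = 3), 14-fold (log2 3.81 ± 0.15, adjusted p = 2.37e-09). Chac1, a glutathione-degrading enzyme, rose from 27.9 ± 10 to 163 ± 5.6 CPM (5.81-fold, log2 2.54 ± 0.23, adjusted p = 8.74e-05), and Ddit3, encoding the transcription factor CHOP, from 8.49 ± 2.7 to 35.3 ± 2.5 CPM (log2 2.04 ± 0.16, adjusted p = 2.01e-06). Dancr, a long non-coding RNA, fell from 28 ± 2.8 to 7.42 ± 0.35 CPM (3.78-fold, log2 -1.92 ± 0.10, adjusted p = 1.33e-09). The series text names the comparison of each starved group with its control as the purpose, and each ± after a log2 value is an SE (n = 3 per group). Further genes that rose were Gm45847, a non-coding RNA (log2 3.32 ± 0.22), Inhbe, an inhibin subunit (2.96 ± 0.25), Hrk, a pro-apoptotic BH3-only protein (2.78 ± 0.17), Trpm1 (2.57 ± 0.26), Vldlr, a lipoprotein receptor (2.48 ± 0.16), and Tmem86a (2.35 ± 0.14). Further genes that fell were Fgf18 (-1.76 ± 0.10), Cbr3 (-1.74 ± 0.15), Ddit4l (-1.61 ± 0.19), Zc3h12a, an endoribonuclease (-1.54 ± 0.13), and Fgf15 (-1.46 ± 0.12). In all, 6608 of 16140 genes were called, 3379 higher and 3229 lower, of which 545 and 198 had a log2 fold change of at least 1.

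Integrated stress response (ISR) genes, which act in the programme run by eIF2α kinases and ATF4, rose together. Of 22 ISR regulators tested, 19 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.96, adjusted p = 1.8e-16, or 0.156 with estimated correlation), where the median is that of the log2 fold changes of the tested members. Trib3, a pseudokinase, rose by 1.54 ± 0.19, adjusted p = 0.000307, Atf4 by 0.44 ± 0.09, adjusted p = 0.00187, Cdkn1b by 0.66 and Cebpg by 0.65. Atf5 was the one that fell (-0.27), and Sesn2 (0.00 ± 0.07, adjusted p = 0.967) was called only with the replicate block and a GC correction together (log2 0.13, adjusted p = 0.0277). Ddit4 rose by 0.41 ± 0.08, adjusted p = 0.000922 (adjusted p = 0.085 with all 6 groups in the fit). For amino acid synthesis, 9 of 16 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.26, adjusted p = 2.83e-05, or 0.156 with estimated correlation), among them Asns, asparagine synthetase (0.59 ± 0.06, adjusted p = 7.78e-07), Aldh18a1 (0.90) and Mthfd2 (0.84). Among 20 tRNA synthetases, which charge tRNAs with amino acids, 13 rose and 2 fell (13 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.00376, or 0.378 with estimated correlation). Lars stood at 0.67 and Nars at 0.41. Of 17 amino acid transporters, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.52, adjusted p = 3.76e-10, or 0.0638 with estimated correlation). Slc7a11 stood at 2.75 and Slc1a4 at 1.66. Lysosome and autophagy genes moved up as well, and 19 of 29 rose and 3 fell (20 and 3 adjusted over the list alone, median 0.45, adjusted p = 2.96e-10, or 0.104 with estimated correlation), including Mcoln1 (1.25), Fnip1 (1.21) and Neu1 (1.14).

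**Figure D1:**
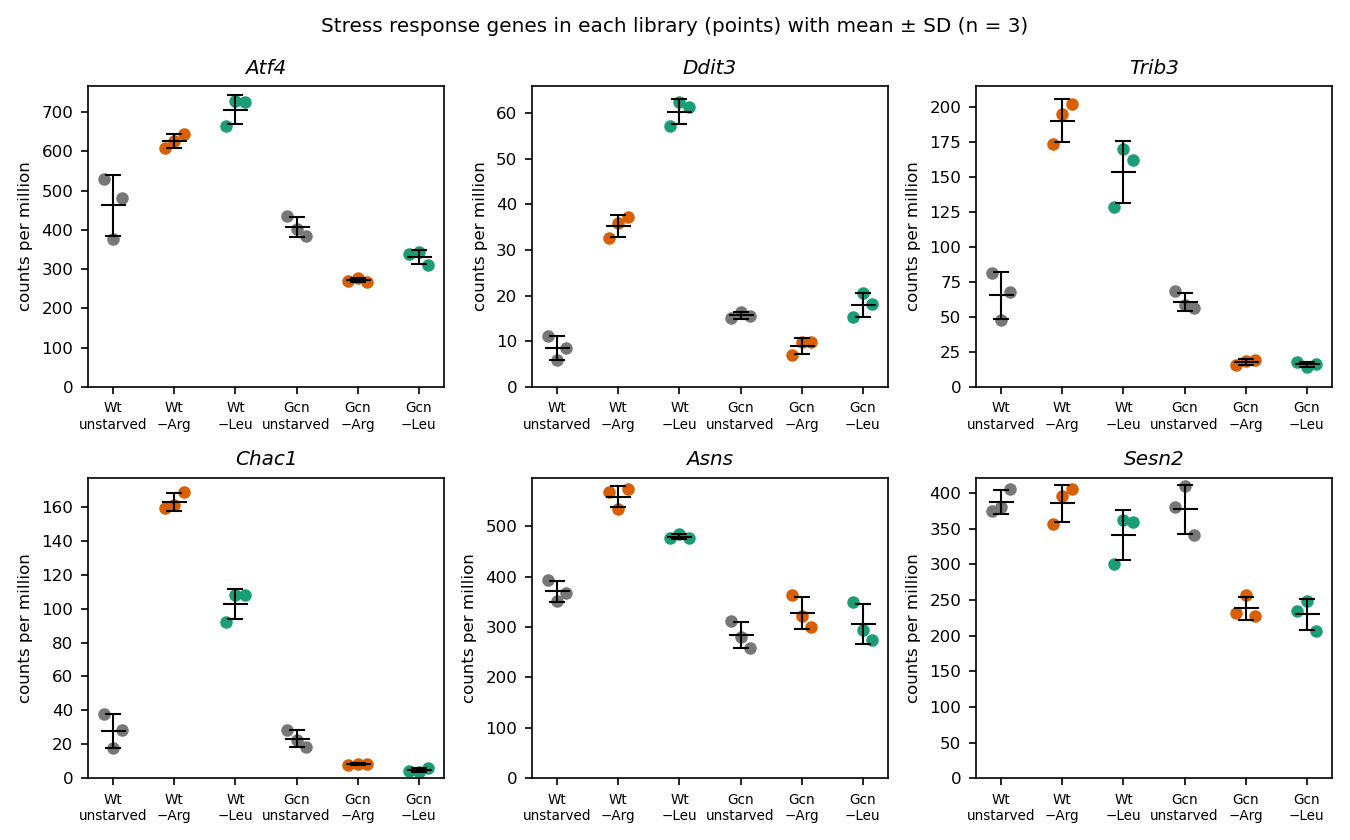
Stress response genes in each library (points, CPM) of the 6 groups, with the mean and SD of 3 libraries per group. Chac1 stands at 163 ± 5.6 CPM in Wt Arg and 8.27 ± 0.61 CPM in Gcn Arg.

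Sterol, redox and ribosome genes moved down in the arginine-starved wild type. Of 20 sterol synthesis genes, 14 fell (14 adjusted over the list alone, median -0.37, adjusted p = 0.000164, or 0.439 with estimated correlation). Among 13 NRF2 antioxidant genes, 10 fell (11 adjusted over the list alone, median -0.41, adjusted p = 3.43e-06, or 0.107 with estimated correlation). Srxn1 stood at -1.21. For p53 targets, 2 of 19 rose and 13 fell (2 and 13 adjusted over the list alone, median -0.44, adjusted p = 4.61e-06, or 0.329 with estimated correlation). Phlda3 stood at -1.33. Of 14 heat shock genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone, median -0.14, adjusted p = 0.033, or 0.329 with estimated correlation). Hspa1b stood at -1.62. Among 79 ribosomal protein genes, 25 fell (22 adjusted over the list alone, median -0.21, adjusted p = 0.000164, or 0.743 with estimated correlation). Of 28 ribosome biogenesis genes, 4 rose and 13 fell (4 and 14 adjusted over the list alone, median -0.10, adjusted p = 0.033, or 0.343 with estimated correlation).

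Replication genes and histone transcripts moved up. Of 20 replication genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.033, or 0.329 with estimated correlation). Among 19 histone transcripts, which largely lack poly(A) tails and serve here as a sign of RNA quality, 10 rose (10 adjusted over the list alone, median 0.62, adjusted p = 0.00474, or 0.354 with estimated correlation). Hist1h1c stood at 0.83, Hist1h1b at 1.68 and Hist1h1e at 2.06. No other list was called. The call of heat shock genes was lost without Wt Unstarved 2 or Wt Arg 3 (highest adjusted p = 0.0617), that of ribosome biogenesis without Wt Unstarved 1 (highest adjusted p = 0.0558), with library size only (adjusted p = 0.0572) and with the replicate block (adjusted p = 0.0513), and that of replication without Wt Arg 1 (highest adjusted p = 0.0616). Fold changes correlated with GC content across genes (Spearman's rho -0.319 over 13391 genes, which are not independent replicates), and 5865 of the 6608 calls were shared with a GC correction and the replicate block together. Under both, 67 ribosomal protein genes fell, and 15 histone transcripts and 7 replication genes rose.

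Leucine starvation of wild-type cells raised Bhlhe41 to 36.3 ± 7.2 CPM (SD, n = 3), 8.05-fold (log2 3.01 ± 0.16, adjusted p = 7.95e-08), Ddit3 to 60.3 ± 2.8 CPM, 7.02-fold (log2 2.81 ± 0.16, adjusted p = 4.03e-07), and Chac1 to 103 ± 9.1 CPM, 3.66-fold (log2 1.87 ± 0.23, adjusted p = 0.000767). Inhbe (2.60 ± 0.25), Gm45847 (2.36 ± 0.24), Runx1t1, a transcriptional corepressor (1.97 ± 0.15), Hrk (1.92 ± 0.17) and Tmem86a (1.86 ± 0.15) followed. Ddit4l (-1.55 ± 0.19), Cbr3 (-1.29 ± 0.14), Dancr (-1.18 ± 0.10), Slc19a2, a thiamine transporter (-1.12 ± 0.08), and Zc3h12a (-1.12 ± 0.13) fell. In all, 4772 of 16140 genes were called, 2497 higher and 2275 lower, with 289 and 85 at a log2 fold change of at least 1.

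ISR regulators moved up with leucine starvation as well, and 17 of 22 rose and 1 fell (17 and 2 adjusted over the list alone, median 0.82, adjusted p = 2.27e-18, or 0.22 with estimated correlation). Atf4 rose by 0.61 ± 0.09, adjusted p = 0.000251, Trib3 by 1.22 ± 0.19, adjusted p = 0.00177, Cdkn1b by 0.72 and Cebpb by 1.42. Ddit4 (-0.07 ± 0.08, adjusted p = 0.572) was not called, and Sesn2 (-0.19 ± 0.07, adjusted p = 0.0647) only with no filter on low counts (adjusted p = 0.0299) and with the replicate block (adjusted p = 0.00283). Of 16 amino acid synthesis genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.0102, or 0.328 with estimated correlation), with Asns at 0.37 ± 0.06, adjusted p = 0.000178 and Mthfd2 at 0.64, and Glul, glutamine synthetase, at -0.40. Among 20 tRNA synthetases, 10 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.0102, or 0.443 with estimated correlation), with Lars, which charges leucine, at 0.50, Aars at 0.43 and Mars at 0.37. For amino acid transporters, 8 of 17 rose and 1 fell (12 and 2 adjusted over the list alone, median 0.25, adjusted p = 1e-05, or 0.155 with estimated correlation). Slc1a4 stood at 1.32. Of 29 lysosome and autophagy genes, 15 rose and 2 fell (18 and 2 adjusted over the list alone, median 0.29, adjusted p = 8.49e-06, or 0.222 with estimated correlation). Histone transcripts moved the same way, and 6 of 19 rose (8 adjusted over the list alone, median 0.58, adjusted p = 0.0248, or 0.443 with estimated correlation). Hist1h1e stood at 1.81.

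Of 20 sterol synthesis genes with leucine starvation, 1 rose and 9 fell (1 and 9 adjusted over the list alone, median -0.25, adjusted p = 8.24e-05, or 0.443 with estimated correlation). Of 13 NRF2 antioxidant genes, 9 fell (10 adjusted over the list alone, median -0.41, adjusted p = 1.1e-09, or 0.083 with estimated correlation). Among 19 p53 targets, 1 rose and 11 fell (2 and 12 adjusted over the list alone, median -0.33, adjusted p = 6.58e-07, or 0.328 with estimated correlation). For heat shock genes, 5 of 14 fell (6 adjusted over the list alone, median -0.15, adjusted p = 0.00791, or 0.326 with estimated correlation). Of 28 ribosome biogenesis genes, 3 rose and 9 fell (3 and 9 adjusted over the list alone, median -0.09, adjusted p = 0.0187, or 0.328 with estimated correlation), with Rrp9, a U3 snoRNP protein, at -0.87 and Polr1b at -0.50. Of 79 ribosomal protein genes, 8 fell (0 adjusted over the list alone, median -0.11, adjusted p = 0.00298, or 0.74 with estimated correlation). At an unadjusted p under 0.05, edgeR found 15 of them lower, and DESeq2 called 11 and limma-voom 9. The remaining lists were not called. The ribosomal protein call was lost without Wt Leu 3 (highest adjusted p = 0.0911) and the histone call without Wt Unstarved 1 (highest adjusted p = 0.124).

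In cells without GCN2, arginine starvation raised Bhlhe41 from 3.56 ± 0.4 to 34.3 ± 4 CPM (SD, n = 3), 9.69-fold (log2 3.28 ± 0.14, adjusted p = 3.7e-08). Trib3 fell from 60.8 ± 6.4 to 17.7 ± 2 CPM, 3.42-fold (log2 -1.77 ± 0.12, adjusted p = 4.83e-07), and Chac1 from 23.3 ± 5 to 8.27 ± 0.61 CPM (log2 -1.49 ± 0.18, adjusted p = 5.51e-05). Zc3h12a fell from 20.3 ± 1.2 to 5.04 ± 0.47 CPM (-1.99 ± 0.13). Gadd45g (2.69 ± 0.21), Gata2, a transcription factor (2.44 ± 0.18), Aqp3, an aquaporin (2.38 ± 0.12), Dll1, a Notch ligand (2.36 ± 0.15), Tmem86a (2.24 ± 0.15) and Runx1t1 (2.20 ± 0.19) also rose. Dancr (-1.96 ± 0.16), Vav2 (-1.63 ± 0.10), Mat2a, an S-adenosylmethionine synthetase (-1.61 ± 0.09), and Rbm10, a splicing regulator (-1.59 ± 0.09), also fell. In all, 4583 of 16369 genes were called, 2339 higher and 2244 lower, of which 538 and 206 at a log2 fold change of at least 1. With the replicate block, 7602 were called. With library size only, 3449 were higher and 1397 lower, and the median of all genes moved by 0.12.

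The ISR genes moved down in these cells. Of 21 ISR regulators, 2 rose and 13 fell (2 and 13 adjusted over the list alone, median -0.50, adjusted p = 1.09e-05, or 0.141 with estimated correlation). Among those that fell were Atf4 (-0.58 ± 0.08, adjusted p = 0.000168), Ddit3 (-0.81 ± 0.15, adjusted p = 0.00143), Sesn2 (-0.65 ± 0.10, adjusted p = 0.00029), Gdf15 (-1.22) and Gpt2 (-1.12), while Cdkn1b (0.79) and Gadd45a (0.55) rose. Ddit4 fell (-0.81 ± 0.22, adjusted p = 0.0214), a call lost without Gcn Unstarved 2 (log2 -0.69, adjusted p = 0.0617). Asns was not called (0.22 ± 0.10, adjusted p = 0.139) except with the replicate block (adjusted p = 0.00119, or 0.000411 with a GC correction too) and with library size only (log2 0.34, adjusted p = 0.0341). Among 19 ER chaperones, 1 rose and 9 fell (2 and 9 adjusted over the list alone, median -0.24, adjusted p = 0.000398, or 0.141 with estimated correlation). Herpud1 stood at -1.23. Of 20 tRNA synthetases, 4 fell (1 adjusted over the list alone, median -0.14, adjusted p = 0.0421, or 0.525 with estimated correlation). Tars stood at -0.52 and Cars at -0.34, the latter not called without Gcn Unstarved 1, Gcn Unstarved 2 or Gcn Arg 3 (highest adjusted p = 0.115), with library size only (0.136) or without the 3 Gcn libraries numbered 1 (0.0607). For sterol synthesis, 1 of 20 rose and 12 fell (1 and 12 adjusted over the list alone, median -0.41, adjusted p = 6.86e-06, or 0.14 with estimated correlation). Of 12 fatty acid synthesis genes, 4 fell (8 adjusted over the list alone, median -0.30, adjusted p = 0.0075, or 0.53 with estimated correlation). Scd1 stood at -0.91. Of 20 glycolysis and hypoxia genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone, median -0.27, adjusted p = 0.0075, or 0.53 with estimated correlation).

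**Figure D2:**
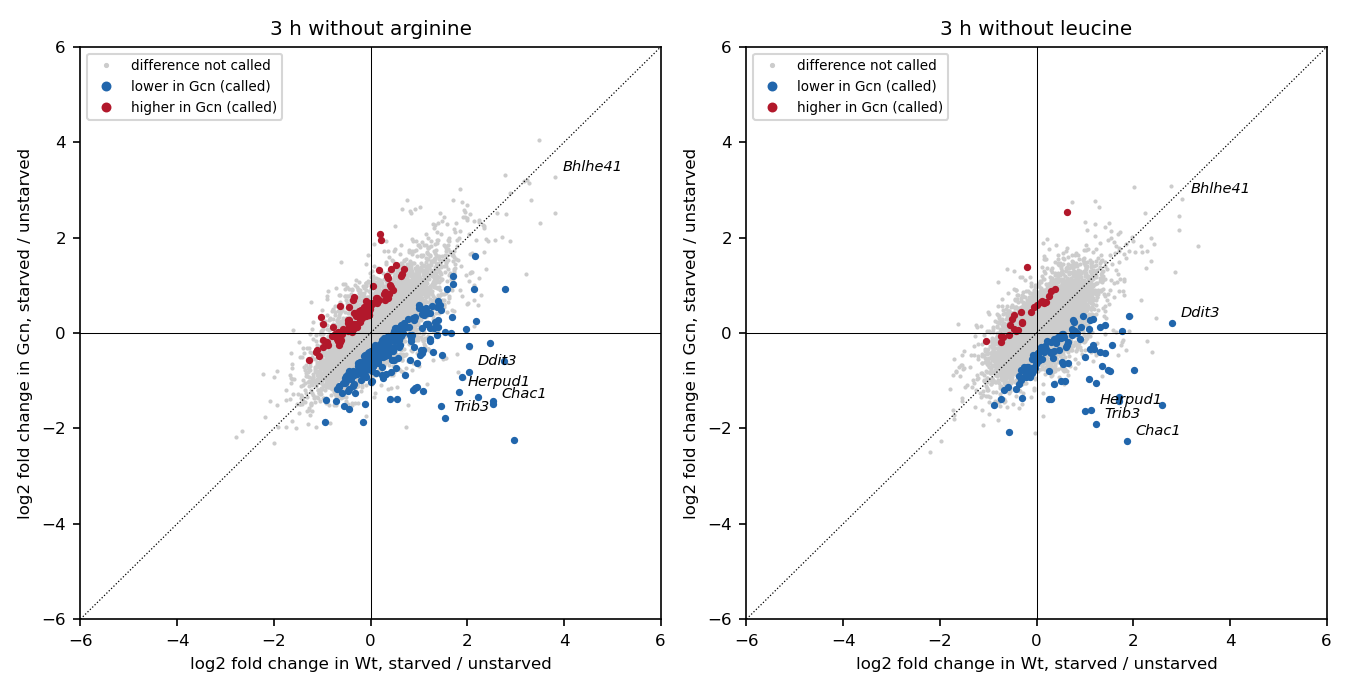
Log2 fold change with starvation in Wt (x axis) and Gcn (y axis) for 15726 genes per panel, for arginine and for leucine. Genes called lower in Gcn by the interaction test are blue, those called higher red and others grey, and Chac1 lies at 2.54 in Wt and -1.49 in Gcn for arginine.

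Heat shock genes also moved down, and 1 of 14 rose and 8 fell (1 and 9 adjusted over the list alone, median -0.36, adjusted p = 0.00214, or 0.378 with estimated correlation). Among 13 NRF2 antioxidant genes, 10 fell (10 adjusted over the list alone, median -0.47, adjusted p = 1.09e-05, or 0.14 with estimated correlation). Of 19 p53 targets, 3 rose and 8 fell (3 and 9 adjusted over the list alone, median -0.27, adjusted p = 0.0356, or 0.53 with estimated correlation). For ribosomal proteins, 10 of 79 fell (7 adjusted over the list alone, median -0.22, adjusted p = 0.0033, or 0.793 with estimated correlation). Of 28 ribosome biogenesis genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone, median -0.16, adjusted p = 0.00515, or 0.449 with estimated correlation). Among 9 mitochondrial transcripts, 3 fell (4 adjusted over the list alone, median -0.26, adjusted p = 0.0356, or 0.495 with estimated correlation). Of 17 two-cell-like genes, 1 fell (1 adjusted over the list alone, median -0.34, adjusted p = 0.0356, or 0.688 with estimated correlation), namely Tdpoz3 (-1.48).

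Lysosomal, naive pluripotency and replication genes moved up. Of 29 lysosome and autophagy genes, 15 rose (16 adjusted over the list alone, median 0.34, adjusted p = 9.22e-10, or 0.14 with estimated correlation). Hexa stood at 1.53. Among 20 naive pluripotency genes, 9 rose and 3 fell (10 and 4 adjusted over the list alone, median 0.23, adjusted p = 0.0075, or 0.204 with estimated correlation). Tbx3 stood at 1.29 (147 ± 7 to 360 ± 23 CPM), Nr0b1 at 0.81 and Sall4 at 0.69. Of 20 replication genes, 7 rose (8 adjusted over the list alone, median 0.21, adjusted p = 0.00211, or 0.141 with estimated correlation). Uhrf1 stood at 0.72, E2f1 at 0.67 and Cdt1 at 0.49. For leucine catabolism, 5 of 13 rose (5 adjusted over the list alone, median 0.21, adjusted p = 0.0421, or 0.281 with estimated correlation). Of 21 histone transcripts, 3 rose (3 adjusted over the list alone, median 0.40, adjusted p = 0.0356, or 0.546 with estimated correlation). Hist1h1c stood at 0.80 and Hist1h4i at 0.89. No other list was called, except arginine and polyamine metabolism with the replicate block (adjusted p = 0.0382).

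With the replicate block and a GC correction together, 56 ribosomal protein, 14 tRNA synthetase, 14 ER chaperone, 12 glycolysis, 10 two-cell-like and 9 fatty acid synthesis genes fell, and 25 lysosome and autophagy, 14 replication and 8 histone genes rose. Single libraries ended several of the list calls. The tRNA synthetase call was lost without Gcn Unstarved 1, Gcn Arg 1, Gcn Unstarved 2 or Gcn Arg 3 (highest adjusted p = 0.0856) and with library size only (adjusted p = 0.129). That of leucine catabolism was lost without Gcn Unstarved 1, Gcn Arg 1, Gcn Unstarved 2, Gcn Arg 2 or Gcn Unstarved 3 (highest adjusted p = 0.0628), of two-cell-like genes without Gcn Unstarved 1, Gcn Arg 2 or Gcn Unstarved 3 (highest adjusted p = 0.218), of p53 targets without Gcn Arg 1 or Gcn Unstarved 2 (highest adjusted p = 0.0724) and of ribosomal proteins without Gcn Arg 1 or Gcn Unstarved 3 (highest adjusted p = 0.11). The histone call was lost without Gcn Unstarved 2 or Gcn Arg 3 (highest adjusted p = 0.1) and with library size only (adjusted p = 0.0916), and the mitochondrial one without Gcn Unstarved 2 or Gcn Arg 2 (highest adjusted p = 0.0732). Without the 3 Gcn libraries numbered 1, tRNA synthetases (adjusted p = 0.0695), leucine catabolism (0.0519) and two-cell-like genes (0.0894) were not called.

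Leucine starvation of cells without GCN2 lowered Chac1 to 4.76 ± 1.1 CPM (SD, n = 3), 4.82-fold (log2 -2.27 ± 0.18, adjusted p = 6.73e-06), and Trib3 to 16.1 ± 1.6 CPM, 3.77-fold (log2 -1.91 ± 0.12, adjusted p = 7.91e-07). Bhlhe41 rose to 24.8 ± 2.9 CPM, 7-fold (log2 2.81 ± 0.14, adjusted p = 1.28e-07). Gadd45g (2.32 ± 0.21), Runx1t1 (2.01 ± 0.19), Dll1 (1.95 ± 0.15), Tmem86a (1.86 ± 0.15), Klf10, a transcription factor (1.82 ± 0.09), and Txnip, a thioredoxin-interacting protein (1.72 ± 0.11), also rose. Slc6a9, a glycine transporter (-1.63 ± 0.13), Zc3h12a (-1.62 ± 0.12), Herpud1, which acts in ER-associated degradation (-1.62 ± 0.12), Rrp9 (-1.51 ± 0.09) and Ifrd1 (-1.38 ± 0.09) also fell. In all, 3561 of 16369 genes were called, 1920 higher and 1641 lower, with 331 and 106 at a log2 fold change of at least 1. With the replicate block 6651 were called, and without Gcn Unstarved 2 the count was 2171. With library size only, 2609 were higher and 1066 lower.

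Of 21 ISR regulators in the leucine-starved Gcn cells, 3 rose and 12 fell (3 and 14 adjusted over the list alone, median -0.42, adjusted p = 1.79e-06, or 0.186 with estimated correlation). Sesn2 fell (-0.71 ± 0.10, adjusted p = 0.000261), and Atf4 fell (-0.29 ± 0.08, adjusted p = 0.0192), a call lost without Gcn Unstarved 1, Gcn Unstarved 2 or Gcn Leu 3 (highest adjusted p = 0.0762), without the 3 Gcn libraries numbered 1 (adjusted p = 0.0732) and with library size only (adjusted p = 0.0806). Ddit4 fell (-0.75 ± 0.22, adjusted p = 0.0361), a call lost without Gcn Unstarved 2, Gcn Unstarved 3, Gcn Leu 1 or Gcn Leu 3 (highest adjusted p = 0.109). Ndrg1 (0.86), Cdkn1b (0.78) and Gadd45a (0.54) rose, and Ddit3 (0.21 ± 0.14, adjusted p = 0.346) and Asns (0.11 ± 0.10, adjusted p = 0.503) were called only with the replicate block and a GC correction together (adjusted p = 0.0418 and 0.018). For amino acid transporters, 1 of 17 rose and 4 fell (1 and 5 adjusted over the list alone, median -0.17, adjusted p = 0.00769, or 0.363 with estimated correlation), with Slc6a9 and Slc7a5 (-0.65) lower and Slc43a2 (0.72) higher. Of 19 ER chaperones, 5 fell (5 adjusted over the list alone, median -0.11, adjusted p = 0.00076, or 0.186 with estimated correlation). Xbp1 stood at -1.18. Among 20 sterol synthesis genes, 1 rose and 9 fell (1 and 11 adjusted over the list alone, median -0.27, adjusted p = 7.97e-05, or 0.186 with estimated correlation). Of 13 NRF2 antioxidant genes, 9 fell (11 adjusted over the list alone, median -0.44, adjusted p = 1.79e-06, or 0.186 with estimated correlation).

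**Figure D3:**
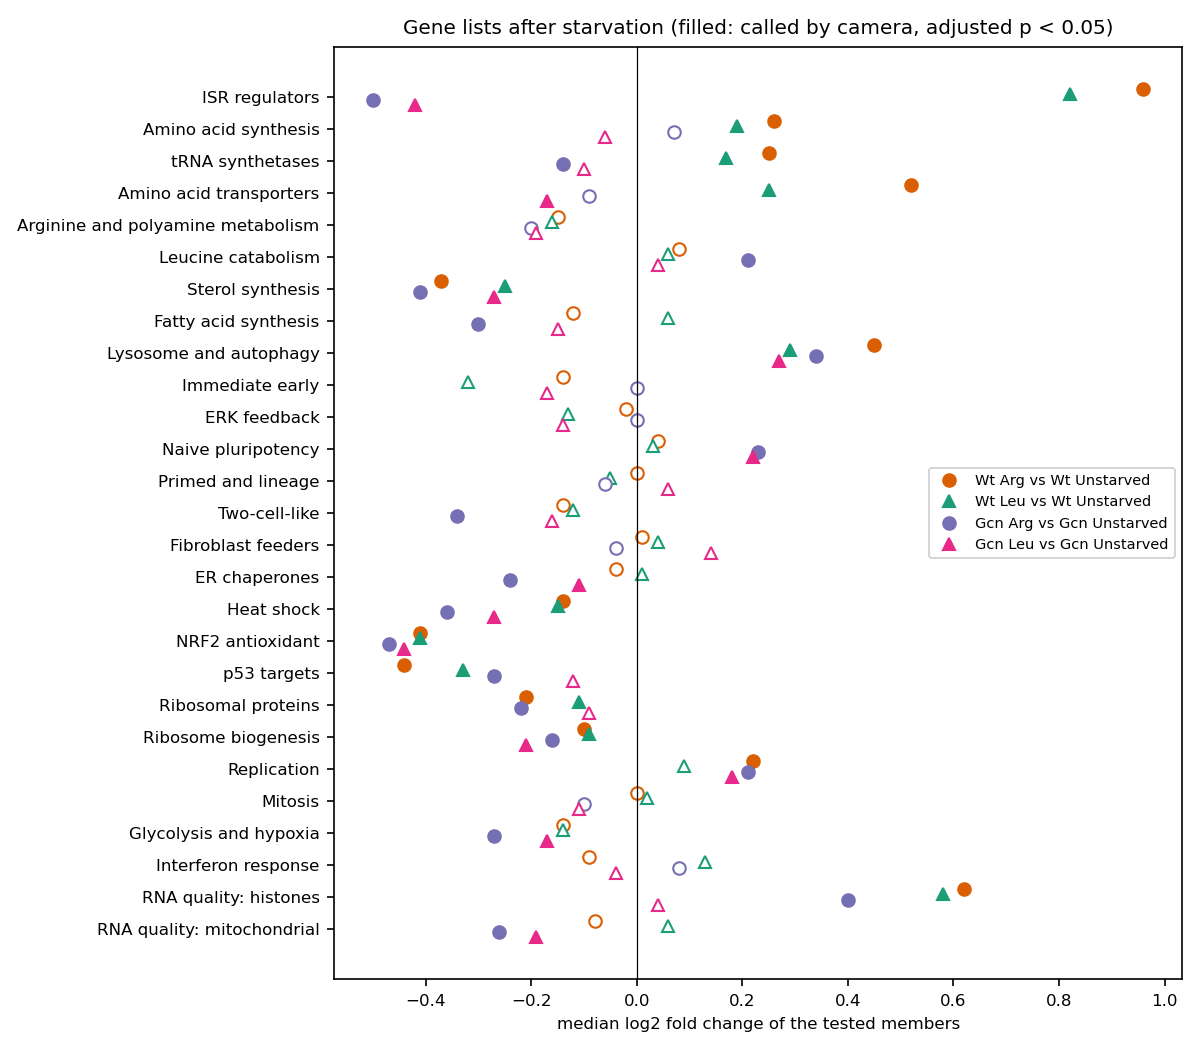
Median log2 fold change of the tested members of each gene list (y axis) in the 4 comparisons of starved with unstarved cells, filled where camera called the list with the preset correlation. ISR regulators have a median of 0.96 in Wt Arg and -0.50 in Gcn Arg.

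Of 14 heat shock genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone, median -0.27, adjusted p = 0.0241, or 0.568 with estimated correlation). Hspa1b (-0.96) and Hspa8 (-0.48) fell and Bag3 (0.47) rose. Among 28 ribosome biogenesis genes, 3 rose and 9 fell (3 and 12 adjusted over the list alone, median -0.21, adjusted p = 0.000704, or 0.357 with estimated correlation). For glycolysis and hypoxia, 1 of 20 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.17, adjusted p = 0.0327, or 0.659 with estimated correlation). Of 9 mitochondrial transcripts, 2 fell (3 adjusted over the list alone, median -0.19, adjusted p = 0.0141, or 0.376 with estimated correlation), namely mt-Rnr1 (-1.04) and mt-Co1 (-0.65). Of 29 lysosome and autophagy genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.27, adjusted p = 6.49e-05, or 0.228 with estimated correlation). Among 20 naive pluripotency genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.00401, or 0.186 with estimated correlation). Of 20 replication genes, 8 rose (8 adjusted over the list alone, median 0.18, adjusted p = 0.00509, or 0.186 with estimated correlation). Under the replicate block and a GC correction, 16 ribosome biogenesis, 11 glycolysis and 9 transporter genes fell and 13 replication genes rose. With the block alone, 5 more lists were called: tRNA synthetases (adjusted p = 0.0411), arginine and polyamine metabolism (0.0437), fatty acid synthesis (0.0265), p53 targets (0.0245) and ribosomal proteins (0.00409). The heat shock call was lost without Gcn Leu 1 (highest adjusted p = 0.084), and that of glycolysis and hypoxia without Gcn Unstarved 2 or Gcn Leu 3 (highest adjusted p = 0.229) and with library size only (adjusted p = 0.0568).

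Leucine was compared with arginine starvation within each genotype to find genes that responded differently. In Wt, the leucine-starved cells had more Fgf18 (log2 1.14 ± 0.11, adjusted p = 9.49e-06), Tmem109 (0.94 ± 0.08, 34.1 ± 2.6 against 17.7 ± 0.47 CPM), Prpf38a (0.94 ± 0.07) and Ngdn (0.91 ± 0.06). They had less Vldlr (-0.96 ± 0.14), Egr1 (-0.88 ± 0.11) and Hrk (-0.86 ± 0.14). In Gcn, leucine-starved cells had more Rbm10 (1.51 ± 0.09, adjusted p = 2.92e-06, 81.8 ± 5.9 against 28.6 ± 2.9 CPM), Tmem109 (1.39 ± 0.10), Plekha2 (1.38 ± 0.21), Ngdn (1.36 ± 0.13) and Rpp25l (1.18 ± 0.11). Lower were Hps4 (-1.19 ± 0.13), Rfesd (-1.14 ± 0.16) and Abtb2 (-0.99 ± 0.14).

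In Wt, 1615 genes were called between leucine and arginine starvation (847 higher and 768 lower with leucine, 13 and 16 at a log2 fold change of at least 1), 3328 with the replicate block and 916 with all 6 groups in the fit. Without Wt Arg 2, Wt Arg 3, Wt Leu 2 or Wt Leu 3, the counts were 871, 1022, 1023 and 987. In Gcn, 1395 were called (760 higher and 635 lower, 32 and 27 at a log2 fold change of at least 1), 4362 with the replicate block and 2344 with all 6 groups. Without Gcn Leu 2 or Gcn Arg 3 there were 710 and 711, and with library size only 610 were higher and 781 lower.

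Of 17 amino acid transporters in Wt, 7 were lower (12 adjusted over the list alone, median -0.27, adjusted p = 6.8e-07, or 0.178 with estimated correlation) with leucine than with arginine starvation. Among 16 amino acid synthesis genes, 5 were lower (6 adjusted over the list alone, median -0.13, adjusted p = 0.000215, or 0.362 with estimated correlation). Aldh18a1 stood at -0.54 and Cth at -0.39. Of 29 lysosome and autophagy genes, 1 was higher and 8 were lower (1 and 10 adjusted over the list alone, median -0.17, adjusted p = 6.8e-07, or 0.206 with estimated correlation). Of 22 ISR regulators, 3 were higher and 4 were lower (3 and 9 adjusted over the list alone, median -0.22, adjusted p = 0.03, or 0.998 with estimated correlation), with Ddit3 (0.77), Cebpb (0.47) and Ndrg1 (0.26) higher and Nupr1 (-0.62) and Ddit4 (-0.49) among the lower ones. For ERK feedback, 1 of 12 was higher and 3 were lower (1 and 3 adjusted over the list alone, median -0.14, adjusted p = 0.0163, or 0.373 with estimated correlation). Dusp6 stood at -0.54 and Spred2 at 0.28. Among 20 replication genes, 3 were lower (4 adjusted over the list alone, median -0.09, adjusted p = 0.03, or 0.373 with estimated correlation). The 79 ribosomal protein genes were called as a list (median 0.08, adjusted p = 0.0327, or 0.998 with estimated correlation) although 0 single members were called by edgeR, also adjusted over the list alone, by DESeq2 or by limma-voom, with 4 higher at an unadjusted p under 0.05. The ISR call was lost without Wt Leu 1, Wt Arg 2 or Wt Arg 3 (highest adjusted p = 0.241) and with the replicate block (adjusted p = 0.102), the ERK feedback call without Wt Leu 1 (highest adjusted p = 0.127), the ribosomal protein call without Wt Leu 1, Wt Leu 2 or Wt Arg 3 (highest adjusted p = 0.867) and the replication call without Wt Arg 1 or Wt Leu 1 (highest adjusted p = 0.127). Of 29 lysosome and autophagy genes in Gcn, 7 were lower (1 higher and 9 lower adjusted over the list alone, median -0.16, adjusted p = 0.000406, or 0.917 with estimated correlation). Fry did not call this list (adjusted p = 0.0687). Gabarapl1 stood at -0.59, and ribosomal proteins were called only with the replicate block (adjusted p = 0.000734). Under the replicate block and a GC correction, 9 ribosomal protein genes were higher in Wt, and 13 (Wt) and 17 (Gcn) lysosome and autophagy genes lower. No other list was called in either genotype.

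Across genes, the share of arginine codons correlated with the fold change of leucine over arginine starvation. Arginine-rich genes were lower in arginine than in leucine starvation. Spearman's rho was 0.198 over 13391 genes in Wt and 0.094 over 13410 genes in Gcn. Both were the highest of the 20 amino acids. The permutation p (1e-05, the smallest possible, ignoring spread between libraries) does not test this rank, and most others in Wt share it. The partial correlation was 0.135 and 0.073. The arginine codon AGA went the other way (-0.090 and -0.019, partial 0.045 and 0.028), and GC content alone gave 0.199 and 0.058. Leucine codons gave -0.091 and -0.076 (partial -0.113 and -0.075). Genes are not independent replicates. In Wt the median arginine share was 6.92% in genes called lower in arginine than in leucine starvation, 5.13% in those called higher and 5.64% in those not called. In Gcn these were 6.25%, 5.44% and 5.65%.

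**Figure D4:**
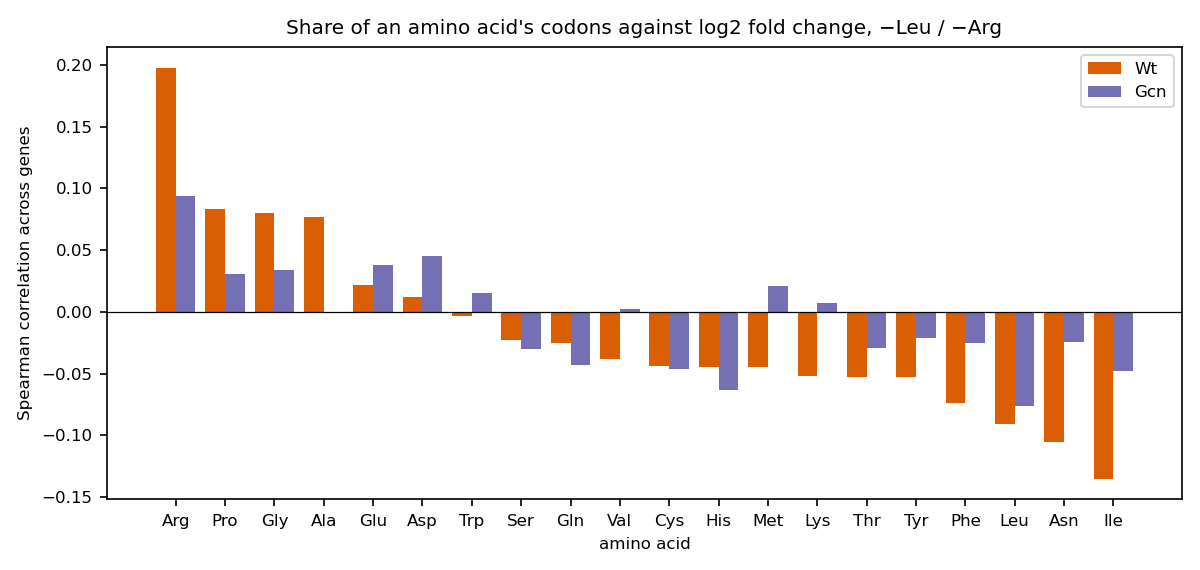
Spearman's rho across genes (bars) between each amino acid's share of codons and the log2 fold change of leucine over arginine starvation, in Wt and Gcn. Arginine stands highest at 0.198 and 0.094.

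Between the unstarved genotypes, which show the baseline from which starvation was applied, H19, an imprinted non-coding RNA, stood at 54.8 ± 8.6 CPM in Wt and 1.48 ± 0.3 in Gcn (SD, n = 3), 36.6-fold lower (log2 -5.19 ± 0.25, adjusted p = 1.48e-10). The keratins Krt8 (103 ± 9.6 against 9.31 ± 0.53 CPM, -3.46 ± 0.10), Krt18 (-3.73 ± 0.11) and Krt19 (-3.95 ± 0.17), the serine protease Prss23 (-4.10 ± 0.26) and the actin-binding Tagln (-3.85 ± 0.21) were also lower in Gcn. Higher were Pnma5 (10.4 ± 1.3 against 60.3 ± 8 CPM, 2.54 ± 0.12), Slfn9 (2.55 ± 0.19), Xlr3c (2.51 ± 0.17), Lars2 (2.47 ± 0.65, adjusted p = 0.0109) and Gm23935 (2.49 ± 0.71, adjusted p = 0.017, adjusted p = 0.0652 without Wt Unstarved 1). Lars2, on chromosome 9, varied widely in the Wt libraries (293 ± 170 against 1620 ± 320 CPM). Of the stress genes, Ddit3 was higher (0.87 ± 0.17, adjusted p = 0.000474), Asns lower (-0.39 ± 0.09, adjusted p = 0.002) and Ddit4 lower (-0.64 ± 0.18, adjusted p = 0.0111, adjusted p = 0.0571 without Gcn Unstarved 1), and Sesn2 (-0.04 ± 0.09, adjusted p = 0.804) and Trib3 (-0.11 ± 0.15, adjusted p = 0.644) were not called. Atf4 (-0.18 ± 0.09, adjusted p = 0.132) and Chac1 (-0.27 ± 0.21, adjusted p = 0.376) were called lower only without Wt Unstarved 2 (log2 -0.31, adjusted p = 0.0049, and -0.51, adjusted p = 0.0203). In all, 5548 of 16924 genes were called, 2802 higher and 2746 lower in Gcn, with 566 and 666 at a log2 fold change of at least 1. Fold changes correlated with GC content (rho -0.340 across 13724 genes), and 4319 of the calls were shared after a GC correction.

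Of 17 two-cell-like genes, which mark a rare state resembling the early embryo, 17 were higher (17 adjusted over the list alone, median 2.02, adjusted p = 2.37e-20, or 0.0319 with estimated correlation) in Gcn. Zfp352 stood at 2.60 and Zscan4d at 2.07, families whose members share reads. Among 19 ER chaperones, 17 were higher (17 adjusted over the list alone, median 0.51, adjusted p = 6.08e-10, or 0.0372 with estimated correlation). Xbp1 stood at 0.80 and Hsp90b1 at 0.67. Of 21 histone transcripts, 11 were higher (11 adjusted over the list alone, median 0.88, adjusted p = 0.000472, or 0.306 with estimated correlation). For primed and lineage markers, 2 of 20 were higher and 10 were lower (2 and 10 adjusted over the list alone, median -0.66, adjusted p = 1.25e-12, or 8.56e-05 with estimated correlation), with T at -4.04 and Cdx2 at -2.91 lower and Otx2 (1.01) and Sox1 (0.80) higher. Of 11 fibroblast markers, 6 were lower (6 adjusted over the list alone, median -0.98, adjusted p = 5.9e-09, or 0.000883 with estimated correlation). Col3a1 stood at -3.95 and Acta2 at -2.94, while Thy1 (0.12), Twist1 (0.01) and Pdgfra (0.37) were not called. Among 21 immediate early genes, 1 was higher and 12 were lower (1 and 13 adjusted over the list alone, median -0.51, adjusted p = 2.88e-06, or 0.0319 with estimated correlation), with Ccn1 at -1.82 and Zfp36 at -1.39 lower and Egr1 at 1.21 higher. Of 16 amino acid synthesis genes, 12 were lower (12 adjusted over the list alone, median -0.38, adjusted p = 7.17e-06, or 0.105 with estimated correlation). Cth stood at -0.87, Psat1 at -0.66 and Phgdh at -0.62. For ERK feedback, 1 of 12 was higher and 6 were lower (1 and 6 adjusted over the list alone, median -0.28, adjusted p = 0.00958, or 0.299 with estimated correlation), with Dusp5 at -1.03 lower and Etv5 at 0.22 higher. Of 13 NRF2 antioxidant genes, 8 were lower (8 adjusted over the list alone, median -0.26, adjusted p = 0.0174, or 0.227 with estimated correlation). No other list was called.

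The arginine interaction tests whether the change with arginine starvation differs between the genotypes. The change in Gcn minus that in Wt was -4.03 ± 0.32, adjusted p = 2.46e-06 for Chac1, which rose in Wt and fell in Gcn, a 16.4-fold difference (n = 3 per group). Adm2, a secreted peptide (-3.58 ± 0.29, 11.9-fold), Trib3 (-3.32 ± 0.22, 10-fold), Herpud1 (-3.08 ± 0.18), Slc6a9 (-2.99 ± 0.19) and Ddit3 (-2.87 ± 0.24, adjusted p = 2.8e-07) followed. Atf4 (-1.02 ± 0.13, adjusted p = 4.99e-05) and Sesn2 (-0.66 ± 0.13, adjusted p = 0.00602) were also lower. So was Ddit4 (-1.24 ± 0.25, adjusted p = 0.0155), but not called without Wt Unstarved 3, Wt Arg 2 or Gcn Unstarved 2 (highest adjusted p = 0.0528). Asns (-0.38 ± 0.13, adjusted p = 0.118) was called only with no filter on low counts (adjusted p = 0.0315) and with the replicate block (adjusted p = 0.000251). Higher in Gcn were Abtb2 (1.15 ± 0.18), the transcription factor Cebpd (1.05 ± 0.17), the small GTPase Rhob (0.92 ± 0.12, 18.9 ± 1.1 to 37.1 ± 3.3 CPM in Gcn and 33 ± 2.8 to 34.4 ± 2.2 in Wt) and Id1 (0.83 ± 0.16). Sox21 (0.89 ± 0.20, adjusted p = 0.0167) was called, but not without Wt Unstarved 1, Wt Arg 2, Wt Arg 3 or Gcn Arg 2 (highest adjusted p = 0.0601) or with a GC correction (log2 0.67, adjusted p = 0.0579). Aldh1b1, an aldehyde dehydrogenase (0.91 ± 0.24, adjusted p = 0.0477), was called, but not without any of Wt Unstarved 1, Wt Unstarved 3, Wt Arg 2, Wt Arg 3, Gcn Arg 2 or the 3 Gcn Unstarved libraries (highest adjusted p = 0.189), by limma-voom or with a GC correction (adjusted p = 0.0655 each), or without the 3 Gcn libraries numbered 1 (0.0669).

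In all, 390 of 16924 genes were called, 105 higher and 285 lower in Gcn, with 9 and 61 at a log2 difference of at least 1. The count was 777 with no filter on low counts and 788 with DESeq2, 2505 (1000 higher, 1505 lower) with a replicate block, where the lowest correlation of pairs, 0.096, missed the bound of 0.1 that arginine starvation passed in each genotype, and with library size only 298 were higher and 162 lower. Without Wt Unstarved 1, Wt Unstarved 3, Wt Arg 1, Wt Arg 2 or Wt Arg 3 it was 248, 223, 245, 209 and 236. Without Gcn Unstarved 1, Gcn Unstarved 2 or Gcn Arg 2 it was 254, 187 and 195. The differences correlated with GC content (rho 0.380 across 13724 genes), and 264 of the calls were shared after a GC correction.

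Of 22 ISR regulators, 17 were lower (18 adjusted over the list alone, median -1.41, adjusted p = 3.29e-79, or 0.000191 with estimated correlation) in Gcn. Stc2 stood at -2.82, Vldlr at -2.69 and Atf3 at -1.94. Among 17 amino acid transporters, 9 were lower (11 adjusted over the list alone, median -0.50, adjusted p = 6.6e-22, or 0.000673 with estimated correlation). Slc7a11 stood at -3.36 and Slc7a1, which carries arginine, at -1.19. Of 20 tRNA synthetases, 10 were lower (14 adjusted over the list alone, median -0.44, adjusted p = 4.77e-14, or 0.0181 with estimated correlation). For amino acid synthesis, 4 of 16 were lower (1 higher and 10 lower adjusted over the list alone, median -0.35, adjusted p = 8.06e-07, or 0.0774 with estimated correlation). Mthfd2 stood at -1.01 and Cth at -0.56. Of 19 ER chaperones, 3 were lower (1 higher and 11 lower adjusted over the list alone, median -0.30, adjusted p = 4.48e-10, or 0.0478 with estimated correlation). Among 19 p53 targets, 2 were higher (4 adjusted over the list alone, median 0.12, adjusted p = 0.0308, or 0.733 with estimated correlation), namely Cdkn1a (0.62) and Ei24 (0.55). Of 20 glycolysis and hypoxia genes, 1 was lower (2 adjusted over the list alone, median -0.05, adjusted p = 0.0345, or 0.739 with estimated correlation), namely Vegfa (-2.08), and with library size only the list had a median of 0.04 and was not called (adjusted p = 0.0725). The 12 fatty acid synthesis genes were called as a list (median -0.14, adjusted p = 0.0414, or 0.733 with estimated correlation), with 0 called singly by edgeR, 1 lower adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The remaining lists were not called. The fatty acid call was lost without Wt Unstarved 1, Wt Arg 2, Wt Unstarved 3, Wt Arg 3, Gcn Unstarved 1, Gcn Unstarved 2, Gcn Arg 2 or Gcn Arg 3 (highest adjusted p = 0.12) and with library size only (adjusted p = 0.0836), the p53 call without Wt Arg 1, Wt Unstarved 2, Gcn Unstarved 1, Gcn Arg 2 or Gcn Arg 3 (highest adjusted p = 0.263) and the glycolysis call without Wt Unstarved 1, Wt Unstarved 2, Wt Arg 3, Gcn Unstarved 2 or Gcn Arg 3 (highest adjusted p = 0.278).

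For leucine, the change in Gcn minus that in Wt was -4.15 ± 0.32, adjusted p = 2.66e-06 for Chac1, a 17.8-fold difference, again with opposite signs. Trib3 (-3.15 ± 0.22, 8.87-fold), Adm2 (-3.06 ± 0.28), Herpud1 (-2.76 ± 0.18), Slc6a9 (-2.64 ± 0.19) and Ddit3 (-2.61 ± 0.23, adjusted p = 8.85e-07) followed. Atf4 (-0.91 ± 0.13, adjusted p = 0.000344) was also lower, and Ddit4 (-0.69 ± 0.25, adjusted p = 0.233) and Asns (-0.26 ± 0.13, adjusted p = 0.367) were called only with the replicate block (adjusted p = 0.000234 and 0.00816). Sesn2 (-0.53 ± 0.13, adjusted p = 0.0489) was called, but not without any of the 3 Wt Unstarved libraries, Wt Leu 2, Wt Leu 3, Gcn Unstarved 1, Gcn Unstarved 2, Gcn Leu 1 or Gcn Leu 3 (highest adjusted p = 0.168). Nor was it with RLE scaling (adjusted p = 0.0518), library size only (0.0776), limma-voom (0.0532) or without the 3 Gcn libraries numbered 1 (0.101). Higher in Gcn were Btg2 (0.88 ± 0.17, 103 ± 16 to 49.7 ± 4.4 CPM in Wt and 89.1 ± 7.3 to 79 ± 11 in Gcn), Rpp25l (0.83 ± 0.14), Cdkn1a, the cell cycle inhibitor p21 (0.80 ± 0.15), and Itpripl1 (0.70 ± 0.13). Epp13 (0.74 ± 0.17, adjusted p = 0.0384) was called, but not without any of Wt Unstarved 1, Wt Unstarved 3, Wt Leu 1, Wt Leu 2, Gcn Leu 1 or the 3 Gcn Unstarved libraries (highest adjusted p = 0.123). Gfod2 (0.66 ± 0.14, adjusted p = 0.0218) was called, but not without Wt Unstarved 3, Wt Leu 1, Wt Leu 2, Gcn Unstarved 1, Gcn Unstarved 2 or Gcn Leu 2 (highest adjusted p = 0.078). Neither was called without the 3 Gcn libraries numbered 1 (adjusted p = 0.137 and 0.0742).

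In all, 139 of 16924 genes were called, 26 higher and 113 lower in Gcn, with 2 and 39 at a log2 difference of at least 1. The count was 353 with no filter on low counts and 383 with DESeq2, 1878 (749 higher, 1129 lower) with a replicate block (lowest correlation of pairs 0.049), and with library size only 80 were higher and 77 lower. Without Wt Unstarved 3, Wt Leu 1, Wt Leu 2 or Wt Leu 3 it was 80, 91, 87 and 85. Without Gcn Unstarved 1, Gcn Unstarved 2, Gcn Leu 2 or Gcn Leu 3 it was 85, 74, 82 and 257.

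Of 22 ISR regulators in the leucine interaction, 15 were lower (18 adjusted over the list alone, median -1.10, adjusted p = 3.68e-75, or 0.000272 with estimated correlation). Gdf15 stood at -2.27, Stc2 at -2.26 and Cebpb at -1.84. Among 17 amino acid transporters, 6 were lower (1 higher and 10 lower adjusted over the list alone, median -0.37, adjusted p = 1.34e-20, or 0.00105 with estimated correlation). Slc7a11 stood at -3.14 and Slc3a2 at -0.73. For tRNA synthetases, 4 of 20 were lower (9 adjusted over the list alone, median -0.26, adjusted p = 1.99e-09, or 0.0693 with estimated correlation). Of 16 amino acid synthesis genes, 2 were lower (7 adjusted over the list alone, median -0.27, adjusted p = 1.11e-06, or 0.0832 with estimated correlation), namely Mthfd2 (-0.90) and Aldh18a1 (-0.74). Among 19 ER chaperones, 2 were lower (6 adjusted over the list alone, median -0.12, adjusted p = 4.92e-08, or 0.0832 with estimated correlation), namely Herpud1 and Xbp1 (-0.77). Of 19 p53 targets, 1 was higher (3 adjusted over the list alone, median 0.15, adjusted p = 0.0021, or 0.452 with estimated correlation), namely Cdkn1a. Of 21 immediate early genes, 1 was higher (3 adjusted over the list alone, median 0.11, adjusted p = 0.0317, or 0.398 with estimated correlation), namely Btg2. Of 28 ribosome biogenesis genes, 2 were lower (2 adjusted over the list alone, median -0.06, adjusted p = 0.0317, or 0.452 with estimated correlation), namely Rrp9 (-0.65) and Nop14 (-0.64), and with library size only the list had a median of 0.01 and was not called (adjusted p = 0.163).

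Another 3 lists were called although edgeR called 0 of their members in the leucine interaction. For the 20 replication genes (median 0.10, adjusted p = 0.00327, or 0.119 with estimated correlation), 3 were higher adjusted over the list alone, 6 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, with Rrm2 at 0.33 ± 0.10, adjusted p = 0.144. For the 12 fatty acid synthesis genes (median -0.20, adjusted p = 0.0317, or 0.723 with estimated correlation), 3 were lower at an unadjusted p under 0.05, and 0 adjusted over the list alone, by DESeq2 or by limma-voom. For the 9 mitochondrial transcripts (median -0.28, adjusted p = 0.00461, or 0.452 with estimated correlation), 1 was lower at an unadjusted p under 0.05, and 0 adjusted over the list alone, by DESeq2 or by limma-voom. The fatty acid call was lost without Wt Unstarved 1, Wt Leu 2, Wt Unstarved 3, Gcn Unstarved 1, Gcn Leu 2 or Gcn Leu 3 (highest adjusted p = 0.157) and with library size only (adjusted p = 0.0582), the immediate early call without Wt Leu 2, Gcn Unstarved 1, Gcn Leu 2 or Gcn Unstarved 3 (highest adjusted p = 0.111) and without the 3 Gcn libraries numbered 1 (adjusted p = 0.0632). The p53 call was lost without Wt Unstarved 2 (highest adjusted p = 0.077), that of ribosome biogenesis without Wt Leu 2, Wt Unstarved 3, Wt Leu 3, Gcn Unstarved 2 or Gcn Unstarved 3 (highest adjusted p = 0.182) and that of mitochondrial transcripts without Wt Unstarved 1 or Wt Leu 2 (highest adjusted p = 0.1). No other list was called.

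Arginine and leucine starvation shared many calls within a genotype. In Wt, 2066 genes were called higher and 1785 lower with both, among them Bhlhe41 and Dancr, and 42 moved in opposite directions, against 522.8 and 455.1 for independent lists. In Gcn, 1368 were called higher and 1034 lower with both and 30 in opposite directions, against 274.4 and 225 (4678 in the same direction with the replicate block, and 1478 without Gcn Unstarved 2). Fold changes correlated at 0.847 in Wt and 0.794 in Gcn, against means of 0.511 and 0.497 over 20 simulations of unchanged groups set against the same controls. Covariances were 0.1603 and 0.1691, against 0.0207 and 0.0286 in those simulations (differing by 0.1396 and 0.1405). Simulated same-direction overlaps (0 genes on average in Wt, 0.15 in Gcn) are no benchmark, as at most 3 and 4 genes were called. The 3 control libraries cannot be split into parts of at least 2, so part of the excess in overlap may come from sharing them. Between genotypes, which share no library, 1667 genes were called higher and 1574 lower with arginine starvation in both (against 485.7 and 455.9, r = 0.703), and 1217 and 1030 with leucine starvation (against 296.8 and 235.6, r = 0.629), over 15726 genes. With the replicate block these same-direction overlaps were 5017 and 3972.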

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

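The tests of the Atf4 transcript, of 1 deviating library and scaling as causes for the ISR list (from fits set beforehand) and of splits drawn without mirror images were chosen only after the result was seen.

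The effect of starvation differed between the genotypes, by the interaction test, for 390 genes with arginine and 139 with leucine. With arginine, the difference (Gcn minus Wt, log2) was -4.03 for Chac1, -3.58 for Adm2, -3.32 for Trib3, -3.08 for Herpud1, -2.99 for Slc6a9, -2.87 for Ddit3, -1.02 for Atf4, -0.66 for Sesn2 and -1.24 for Ddit4. It was 1.15 for Abtb2, 1.05 for Cebpd, 0.92 for Rhob, 0.91 for Aldh1b1, 0.89 for Sox21 and 0.83 for Id1. With leucine it was -4.15 for Chac1, -3.15 for Trib3, -3.06 for Adm2, -2.76 for Herpud1, -2.64 for Slc6a9, -2.61 for Ddit3, -0.91 for Atf4 and -0.53 for Sesn2, and 0.88 for Btg2, 0.83 for Rpp25l, 0.80 for Cdkn1a, 0.74 for Epp13, 0.70 for Itpripl1 and 0.66 for Gfod2.

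Other splits of the libraries were tried as a test of chance. Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. With edgeR the real split called 1395 to 6608 genes in the 7 such comparisons, and any other 0. For the interactions, 6 of 60 relabellings (a share of 0.1) called at least as many genes as the real one, with a highest other of 4115 for arginine (real 390) and 2386 for leucine (real 139), so by that count chance is not excluded. The 5 others are all among the 26 drawn that exchange starved and unstarved labels in 1 genotype, adding both effects. Keeping per genotype, of each split and its mirror image, only that nearer the real labels drops these exchanges. Then 1 of 100 gave as many, the highest others being 389 against 390 (arginine) and 64 against 139 (leucine). As the real labels set the choice, this share of 0.01 does not exclude chance.

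Of 21 ISR regulators in starved cells without GCN2, 13 fell and 2 rose with arginine starvation (median log2 fold change -0.50, adjusted p = 1.09e-05, or 0.141 with estimated correlation). With leucine starvation 12 fell and 3 rose (median -0.42, adjusted p = 1.79e-06, or 0.186 with estimated correlation). Against 1 deviating library as the cause of the calls with the preset correlation, these held without each single library (highest adjusted p = 0.000107). The choice of scaling stays open: with library size only, which moved the median of all genes by 0.12 at most, the list medians were -0.38 and -0.33 (bootstrap SD 0.19 and 0.15), neither below -0.1 by more than 2 SD. Camera cannot test this, since scaling moves the list and other genes alike. The median of those that fell was nearest to 0 at -0.65 under other scalings and at -0.62 with 1 library left out, but these genes were chosen for falling, so this decides nothing. A lower Atf4 transcript stays open too, since Atf4 itself fell in both starvations, by -0.29 with leucine, a call that several alternatives ended. Apart from the Atf4 transcript, no biological explanation was tested.

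Genes lower in arginine than in leucine starvation were rich in arginine codons. A hypothesis is ribosome stalling there, or another effect of low arginine. The correlation of 0.094 in Gcn missed the bound of 0.1 set in advance, by less than the permutation SD of 0.0086. In Wt 0.198 passed it. The SD ignores spread between libraries. The codon AGA went the other way, though not as a partial correlation, so the hypothesis stays open. Against GC content, coding length and expression as the whole cause, the partial correlation was 0.135 in Wt and 0.073 in Gcn, where such a cause needed under 0.05 in both. The bound of 0.1 set for excluding it was passed in Wt alone. Without 105 splicing factor genes the correlation was 0.194 in Wt and 0.089 in Gcn, read the same way.

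The unstarved genotypes differed in H19, keratins, lineage and fibroblast markers and Lars2. Fibroblast-type or differentiated cells in the Wt cultures cannot be told apart from a difference between the lines: 54.5% of the fibroblast markers were called lower in Gcn (72.7% lay below 0, median -0.98), between the bounds of 80% and 50% set in advance. Their abundant transcripts stood at 78 ± 14 against 5.39 ± 0.99 CPM for Tagln, 28.1 ± 3.8 against 3.65 ± 0.41 for Acta2 and 8.2 ± 1.3 against 1.76 ± 0.2 for Col1a1 (SD, n = 3). For Lars2, leftover ribosomal RNA stays open: its log2 CPM correlated with Gm42418 over 9 libraries at r = 0.878 in Wt (exact permutation p = 0.00604, adjusted 0.0242 over 4 tests, rho = 0.8, p = 0.0138, adjusted 0.0276) and r = 0.703 in Gcn (p = 0.034, adjusted 0.0453, rho = 0.617, p = 0.0857, adjusted 0.0857). Within groups r was 0.869 and 0.649, and without the 2 farthest libraries 0.533 and 0.64.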

How the results depend on the processing

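The fits with a GC correction and without the 3 Gcn libraries numbered 1 were chosen only after the result was seen. Over 320 pairs of named gene and comparison, 5421 values under alternatives were computed: 5271 kept direction and side of the threshold, 106 lost the call, 31 gained it and 13 changed sign. Counts of calls under the settings not named here lay within 1.5 times the main count. Asking for a log2 fold change of at least 1 as well left 743 (Wt Arg), 374 (Wt Leu), 744 (Gcn Arg), 437 (Gcn Leu), 29 (Wt leucine against arginine), 59 (Gcn leucine against arginine), 1232 (unstarved genotypes), 70 (arginine interaction) and 41 (leucine interaction), and overlaps of 301 (both starvations in Wt), 323 (both in Gcn), 321 (arginine in both genotypes) and 145 (leucine in both), by construction. For the others the cause was not tested. The 2 interactions had 777 and 353 calls with no filter on low counts and 788 and 383 with DESeq2. With all 6 groups in the fit, leucine against arginine gave 916 in Wt and 2344 in Gcn. With the correlation estimated from the data, 11 of 91 list calls held.

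With the replicate block, the paired comparisons gave 7602 (Gcn Arg), 6651 (Gcn Leu), 3328 (Wt leucine against arginine) and 4362 (Gcn leucine against arginine), and overlaps of 4678 in Gcn, 5017 for arginine and 3972 for leucine. With the block and a GC correction these 4 counts were 8075, 7173, 3323 and 5044. In paired comparisons the block changed no call of a list or named gene besides those given with the results and mt-Nd6, Zfp809 and Usp17lc (Gcn Arg, adjusted p = 0.0591, 0.023 and 0.00552). Where numbers were not taken to pair the samples, lowest and highest correlations of pairs were 0.054 and 0.23 (Wt Leu), -0.159 and 0.029 (unstarved genotypes), 0.096 and 0.448 (arginine interaction) and 0.049 and 0.463 (leucine interaction). There the block gave 6555, 5904, 2505 and 1878 calls and added the naive pluripotency list in Wt Leu and both interactions and replication in the arginine interaction. Of the 9 libraries per genotype, 9 in Wt and 8 in Gcn correlated best with a library of their own number.

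Leaving out 1 library at a time gave 5513 to 6300 calls (Wt Arg), 3749 to 4537 (Wt Leu), 3212 to 4057 (Gcn Arg), 2171 to 3163 (Gcn Leu), 871 to 1258 and 710 to 1082 (leucine against arginine in Wt and Gcn), 4355 to 5215 (unstarved genotypes), 187 to 525 and 74 to 257 (arginine and leucine interactions), 85 to 98 list calls, and overlaps of 3006 to 3720, 1478 to 2184, 2485 to 3050 and 1573 to 2101. Without the 3 Gcn libraries numbered 1 the counts were 4234 (Gcn Arg), 3291 (Gcn Leu), 1224 (Gcn leucine against arginine), 5433 (unstarved genotypes), 476 and 128 (interactions). The fold changes that turned were of genes not called in the first place. Sesn2 in Wt Arg (0.00) was 0.03 with library size only, -0.04 without Wt Arg 3, 0.03 without Wt Unstarved 3, 0.05 without Wt Arg 1 and 0.13 with the block and GC correction, then called (adjusted p = 0.0277). Ddit4 in Wt Leu (-0.07) was 0.02 with the GC correction. Eif2ak4 in Gcn Arg (0.07) was -0.06 without Gcn Arg 1, -0.01 without Gcn Unstarved 3 and 0.22 without Gcn Arg 2, and in Gcn Leu (-0.15) 0.03 without the 3 Gcn libraries numbered 1. Between unstarved genotypes Trib3 (-0.11) was -0.29 without Wt Unstarved 2, 0.07 without Wt Unstarved 1 and 0.02 with the GC correction, Chac1 (-0.27) was -0.51 and 0.02 without those, and Sesn2 (-0.04) was -0.11 without Gcn Unstarved 2, 0.03 without Gcn Unstarved 3 and 0.08 with the GC correction.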

Other observations

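The tests of naive pluripotency and polyamine genes were planned, and the members given were chosen only after the result was seen. Naive pluripotency genes were not called as a list between the unstarved genotypes: 6 of 20 were higher and 3 were lower (6 and 3 adjusted over the list alone, median 0.08, adjusted p = 0.0816, or 0.63 with estimated correlation). Tbx3 (1.10), Prdm14 (0.88) and Nanog (0.85) were higher in Gcn, and Lefty1 (-1.50) and Dppa3 (-1.15) lower. Of 13 arginine and polyamine genes in Wt Arg, 1 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.15, adjusted p = 0.267, or 0.476 with estimated correlation). Srm, spermidine synthase, stood at -0.44, Amd1 at -0.42 and Azin1, antizyme inhibitor, at 0.48. In Gcn Arg, 3 of 14 fell (3 adjusted over the list alone, median -0.20, adjusted p = 0.0668, or 0.279 with estimated correlation). Those were Amd1 (-0.64), Srm (-0.47) and Odc1, ornithine decarboxylase (-0.34).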
